A study of Arabidopsis thaliana with 12 samples.

How the data were processed

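Total RNA of Arabidopsis thaliana, ecotype Columbia 0, was measured on an array in 12 samples, 6 of wild type (WT) and 6 of the pam46 mutant. Per the labels, pam46 has altered photosynthesis and a defect in an unknown protein. The mutated gene, the tissue, the growth conditions, the array's background correction and its normalization are not given in the sources used here. The values are spot intensities on a linear scale as deposited, running from 0 to a cap of 100, and no step before deposit is stated. Each sample number from 1 to 6 occurs in both groups. Nothing in the labels says that the samples came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

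The table held 3439 features. GEO's platform annotation, which can be old, names 1 gene for 692 of them, several for 870 and none for 1877, and no gene was named from a feature with several. Of the 692 features with 1 gene, 690 were matched to 689 loci of the RefSeq table of assembly TAIR10.1, which was used for names only, and DAL1 and AT1G03660 kept the annotation's name. For AT2G25870, which had 2 features, the feature with the higher mean was kept, leaving 3438 genes or features tested, 691 of them with 1 gene. No coordinates are given, because the build behind the array's annotation is not given in the sources used here. A feature can also bind transcripts of near-identical genes, which applies to the LHCB1 gene LHB1B2.

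The plan fixed before the data were examined left the values unscaled if the samples' sums or medians agreed within 5%, and used quantile normalization otherwise. The highest sum was 1.11 times the lowest and the highest median 1.71 times the lowest, so quantile normalization was used. Normalized values at or below the 5th percentile of all positive values were set to that floor, 0.0278 (-5.17 on the log2 scale), and log2 was taken. Setting values to the floor shrinks the fold changes of genes near it, which therefore depend on where the floor is set. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), pam46 minus WT, with Benjamini-Hochberg adjustment over all 3438 genes or features, and a gene was called changed at an adjusted p under 0.05. Adjusted p-values in the text are from this model unless another is named. Array data give no read depth, and the number of arrays limits the precision.

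Sample numbers were checked on each sample's deviation from its group mean, correlated across genes or features, before any calls were compared. In both groups the pairs 1 and 2, 3 and 4, and 5 and 6 were mutual best partners in all 12 samples. Within these pairs r was 0.26 to 0.67, and between other samples of a group it was -0.58 to -0.19. Taking deviations from the mean of the same 6 samples itself lowers r within a group, so values below 0 do not show opposite deviations. The plan averaged such pairs as repeat readings if every pair exceeded 0.3. The pam46 pair 3 and 4 missed this at 0.26, so 6 samples were compared with 6 as planned, and the fit with consecutive numbers averaged, 3 against 3, is given beside it. The same number in WT and pam46 also deviated together, with r from 0.24 to 0.57 in the 6 pairs, all above the 0.1 set for pairing. In all 12 samples the best partner in the other group had the same number. The consecutive number of the other group also passed 0.1, at 0.13 to 0.42 (median 0.295, against 0.386 for the same number). The numbers thus pair the samples, in part through the pairs of consecutive numbers. This pairing comes from the shared numbers in the labels and this check, and no label says what a number stands for. The fit with the replicate number as a block is an alternative.

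Of 20 gene lists with 339 entries fixed before the data were examined, 18 members were measured, and 2 lists had the 3 measured members required for a list test, the photosystem II subunits and the plastid ribosomal proteins. Photosystem I subunits, light-harvesting complex proteins, the Calvin cycle, tetrapyrrole biosynthesis, fatty acid synthesis and amino acid synthesis had 1 or 2 each. The other 12 lists had no measured member: electron transport and ATP synthase, carotenoid biosynthesis, protein import and thylakoid targeting, plastid chaperones and proteases, antioxidant proteins, photorespiration, starch and sugar metabolism, plastid transcription, jasmonate synthesis, reference genes, senescence markers, and seed and root markers. Lists were tested with camera (preset correlation 0.01), with the estimated correlation and fry beside it. Another 10 lists were written after the array's gene annotation had been seen and before their values were tested.

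Genes were named by a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among called genes with a feature of their own, and of each list with 3 or more measured members the 2 with the smallest p. Because so few list members were on the array, all 18 are given, a choice made from the annotation and not from the values.

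The test was run on simulated data of 3438 genes in 20 runs, with 200 genes changed and the spread within and between consecutive numbers taken from these samples. With 6 samples against 6, it recovered 32.0% of 1.5-fold, 58.8% of 2-fold and 89.7% of 4-fold changes, and 21.8% of its calls were false. With consecutive numbers averaged, it recovered 4.93%, 19.6% and 56.4%, and 2.01% of its calls were false. With the replicate block on 12 samples 29.7% of calls were false. With averaging and the replicate block together, 0.0746%, 0.373% and 26.1% were recovered, and 0.567% of calls were false. These shares depend on how many genes changed, 200 in the simulation against 1413 called in the data, and need not carry over to these data. Alternatives covered the scaling, the floor, a filter on dim features, the features of a gene, the replicate block, averaging, the prior, array weights, a fold threshold and each sample left out. A random block for consecutive numbers (statmod 1.5.0), pairs of numbers left out, neighbours of bright features left out and a correction by neighbours, which subtracts from each value the median deviation, from their own means over all samples, of the features 6 and 12 numbers away on either side, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.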

Results

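The array gave an intensity for 3439 features in 6 WT samples and 6 samples of pam46, an Arabidopsis mutant with altered photosynthesis. Summed intensities were 3494 ± 129 in WT and 3442 ± 114 in pam46 (SD, n = 6 each). Between samples of the same number, WT sums were higher in 5 of 6, by a mean of 51.3 ± 42.7 (SD, exact two-sided sign-flip test, p = 0.0625, the smallest possible being 0.0312). This test takes the 6 differences as independent, which they may not be, since samples with consecutive numbers deviated together. Median intensities differed more, 0.314 ± 0.0190 in WT (range 0.296 to 0.341) and 0.213 ± 0.0111 in pam46 (range 0.199 to 0.226), so every WT sample lay above every pam46 sample. Features listed at 0 numbered 133 to 179 in WT samples and 196 to 317 in pam46 samples. From 2 to 4 features per sample stood at the cap of 100.

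The comparison of pam46 with WT asked which transcripts differ in a plant with altered photosynthesis. Errors and adjusted p-values of the fit without averaging treat samples with consecutive numbers as independent, which they are not, and can be too small. AT1G22700, which encodes PYG7, a factor for photosystem I accumulation, rose 8.58-fold in pam46 (log2 fold change 3.10 ± 0.34 SE, n = 6 per group), with 2 of 6 WT samples at the floor and a log2 fold change from 1.81 to 3.89 as the floor was moved. CHLM, the methyltransferase that acts on magnesium protoporphyrin in chlorophyll synthesis, fell by 1.31 on the log2 scale (± 0.16 SE). The photosystem I subunit gene PSAN fell by 0.86 (± 0.13), though without a call with equal medians (-0.19, adjusted p = 0.317) or after correction by neighbours in feature number (-0.36, 0.427). The photosystem II subunit gene PSBW rose by 0.69 (± 0.16), a call that ended in 3 alternatives given below. PRK, the phosphoribulokinase of the Calvin cycle, rose by 0.63 (± 0.11), and lost its call with consecutive sample numbers averaged and blocked together (adjusted p = 0.0556). In the simulation that fit recovered 0.0746% of 1.5-fold changes. It called 17.65 genes on average there, with 200 changed, against 693 in the data, so this share need not carry over. With the floor used, the largest fitted changes among named genes were a 10.3-fold fall of AT3G52550, with 4 of 6 pam46 samples at the floor, and a 9.40-fold rise of AT3G06870. After correction by neighbours in feature number AT3G06870 was at 2.18 on the log2 scale. With the floor at the 1st percentile AT1G11820 (-5.30) and AT5G48130 (-5.24) were ahead of AT3G52550 (-5.22), and AT2G31800 (4.59) and AT1G22700 ahead of AT3G06870 (3.23).

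Of 3438 genes or features, 1413 changed, 669 higher and 744 lower in pam46. This count treats the samples of a group as independent, although samples with consecutive numbers deviated together. The random block for consecutive numbers estimated a correlation of 0.614 within them. The fit behind this count also leaves out the pairing of WT and pam46 by sample number. With consecutive sample numbers averaged, 3 against 3, 587 changed (275 higher, 312 lower), and 580 of these were also among the 1413, in the same direction. Among the 691 features of 1 gene, 303 changed (154 higher, 149 lower), of which 119 were also called with averaging (63 higher, 56 lower). The split between directions moved with the scaling: 373 higher and 1301 lower on the values as deposited, 382 and 1274 with equal sums, and 899 and 642 with equal medians. The median log2 fold change of all genes was -0.36 on the values as deposited and -0.34 with equal sums, and directions given here are relative to the quantile-normalized scale. Over all 3438 genes or features, called or not, 59.5% had the same sign in all 3 pairs of consecutive numbers, where independent signs give 25%.

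**Figure D1:**
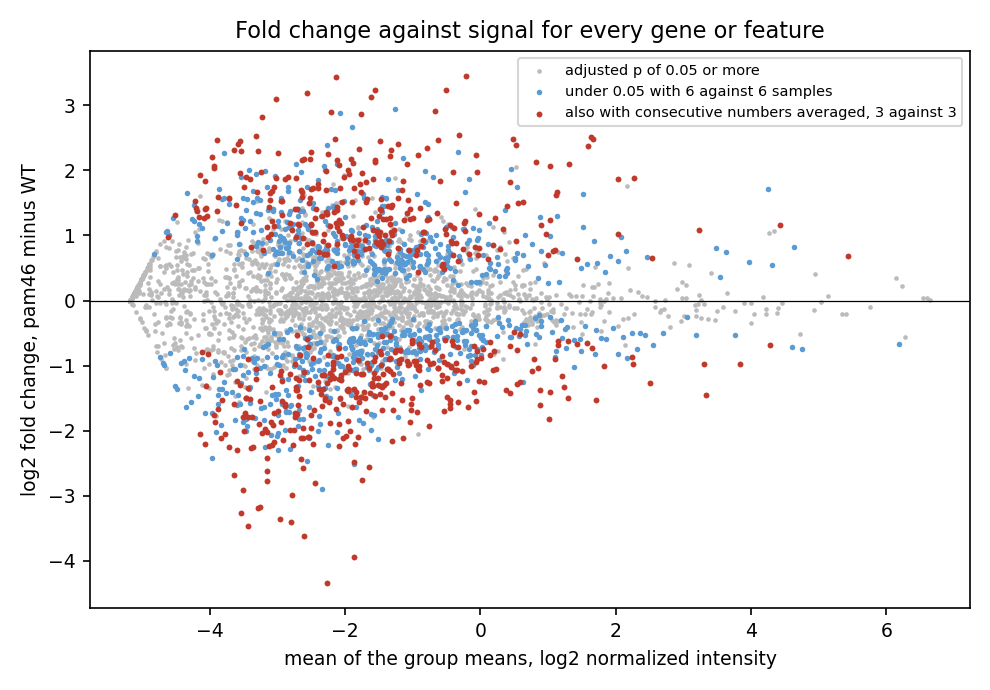
Log2 fold change (pam46 minus WT) of each of the 3438 genes or features against the mean of its group means in log2 normalized intensity. Grey points did not pass, blue points passed with 6 against 6 samples, and red points, 580 in number, passed also with consecutive numbers averaged.

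The 12 largest rises among named genes lay between 2.26 (AT3G56330) and 3.23 (AT3G06870) on the log2 scale, and all 12 were also called with averaging. AT3G56810 rose by 3.23 ± 0.33 (SE), from a deposited intensity of 0.142 ± 0.0567 to 1.13 ± 0.562 (SD, n = 6). AT2G30100 had the smallest error of the group, 2.91 ± 0.10 (adjusted p = 1.68e-08), from 0.275 ± 0.0294 to 1.76 ± 0.179. AT4G35660 rose by 2.49 ± 0.32 and AT5G46560 by 2.34 ± 0.34. AT4G14330, the gene of the phragmoplast kinesin PAKRP2, rose by 2.32 ± 0.42 (adjusted p = 0.00119), and AT3G20150, another kinesin gene, by 1.32 ± 0.25, though without a call on the values as deposited (adjusted p = 0.0693). AT2G31800 rose by 2.47 ± 0.25, with 5 of 6 WT samples at the floor, and ran from 0.66 to 4.59 as the floor was moved. With the floor at the 20th percentile AT4G14330 was at 0.96 and AT5G65490 at 0.99, each still called (adjusted p = 0.0162 and 0.0208), AT3G20490 at 1.14 and AT3G56330 at 1.41, while AT4G14330 was at 3.09 with the floor at the 1st. AT5G65490 (2.45), AT3G20490 (4.92-fold, and 0.81 on the log2 scale after correction by neighbours in feature number) and AT1G72020 (2.27) complete the 12 rises. Every pam46 sample lay above every WT sample in each of them except AT4G14330, as their choice among called genes favours.

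The 12 largest falls lay between -3.36 (AT3G52550) and -1.82 (AT1G04330). AT3G52550 went from a deposited intensity of 0.472 ± 0.0298 in WT to 0.0226 ± 0.0335 in pam46 (SD, n = 6, adjusted p = 1.73e-05). AT1G11820, of the glycosyl hydrolase family that holds beta-glucanases, fell by 2.91 ± 0.24 (SE). AT2G32040, of a plastid folate transporter family, fell by 2.55 ± 0.50. AT2G28200, a zinc finger protein gene, fell by 2.09 ± 0.24. AT5G48130, of the NPH3 family, was at the floor in all 6 pam46 samples and 4.13-fold lower than in WT with the floor used (adjusted p = 8.56e-06). Its log2 fold change was -1.87 with equal medians. With the floor at the 20th percentile it was -0.25 and the call ended (adjusted p = 0.183). AT2G23890 (4.50-fold lower) and AT1G05340 (4.01-fold lower) were also called with averaging. The other 5 were not: AT2G46910, of the fibrillin family of plastid lipid-associated proteins (-2.10, adjusted p = 0.103 with averaging, and -1.27 after neighbour correction), AT3G26730 (-2.07, 0.0856), AT3G53470 (3.99-fold lower, 0.0558), AT1G17744 (-1.89, 0.139, and not called either with the floor at the 1st percentile (0.0848), with the random block (0.0559) or without numbers 1 and 2 (0.0546) or 3 and 4 (0.0758)) and AT1G04330 (-1.82, 0.103). These 5 were called in 27 to 30 of the 31 or 32 alternatives that kept them. In 10 of the 12 at least 1 pam46 sample was at the floor. As the floor was moved, log2 fold changes ran from -5.30 to -1.23 in AT1G11820, -3.77 to -0.70 in AT3G53470 (3 of 6 pam46 samples at the floor), -3.10 to -1.21 in AT3G26730 and -2.92 to -1.22 in AT2G23890. On the values as deposited the 12 rises were 1.41 to 3.15 and the 12 falls -3.63 to -2.21.

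**Figure D2:**
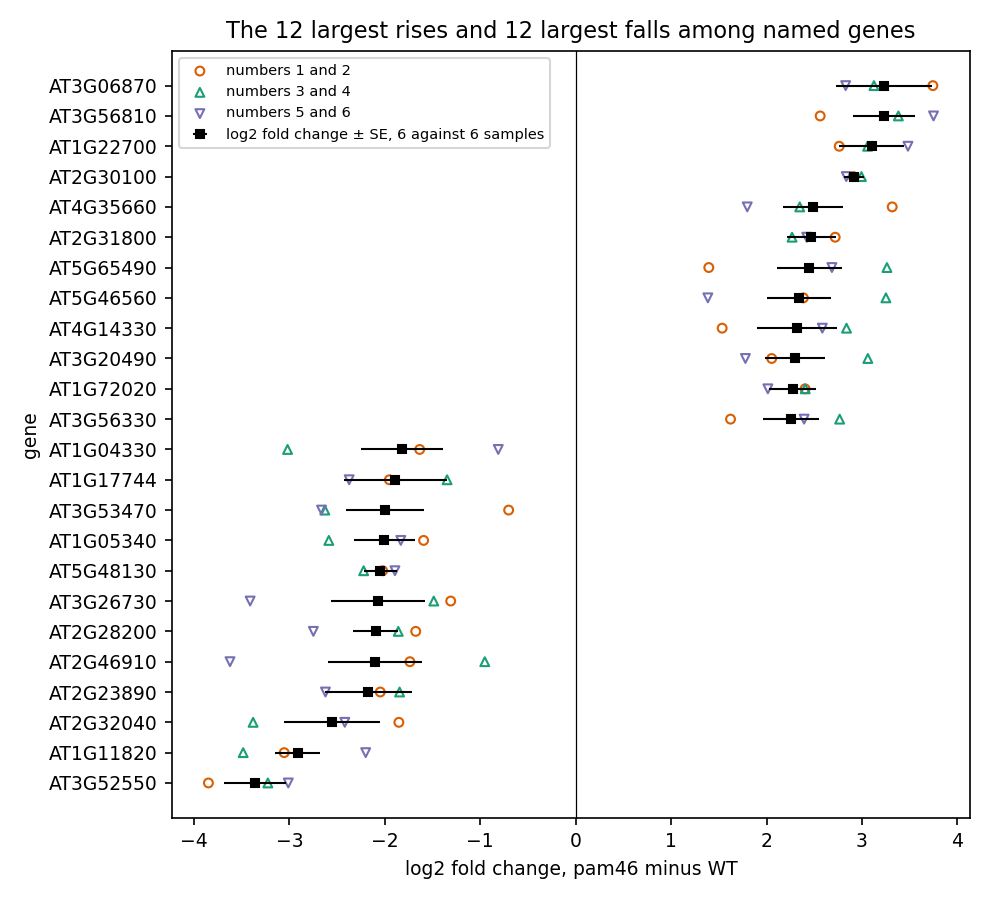
Log2 fold change (pam46 minus WT) of the 12 largest rises and 12 largest falls among named genes. Squares with bars give the fit of 6 against 6 samples ± SE, and open symbols the values of the 3 pairs of consecutive numbers, which share their sign in all 24 genes.

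Of 3 photosystem II genes measured, 1 rose and 2 did not pass, and adjusted over the list alone 2 passed. PSBW rose from a deposited intensity of 30.9 ± 1.47 to 55.8 ± 7.60 (SD, n = 6, adjusted p = 0.00567, and 0.0450 with averaging), and over all alternatives its log2 fold change ran from 0.43 to 1.41 and its adjusted p from 2.92e-06 to 0.115. Its call ended with a random block for consecutive numbers (adjusted p = 0.0967), with averaging and the replicate block together (0.0605) and with correction by neighbours in feature number (0.115), the first and last chosen after seeing the data. PSBY was at -0.38 ± 0.15 (SE, adjusted p = 0.0714, 0.288 with averaging, and 0.0984 with averaging and the block together). It passed as lower in 5 alternatives, the replicate block (0.0159), array weights (0.0346), and without WT sample 3 (0.0221), pam46 sample 5 (0.0423) or numbers 3 and 4 (0.0140). Its sign turned with equal medians (0.22), and after neighbour correction it passed in the other direction (0.55, adjusted p = 0.0473). PSB27 was at 1.28 ± 0.83 (adjusted p = 0.245), from 0.84 to 1.74 with 1 sample left out, and passed in 1 alternative, with numbers 1 and 4, 2 and 5, and 3 and 6 averaged (0.0190). The list as a whole did not pass camera (adjusted p = 0.554, and 0.592 with an estimated correlation).

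Of 6 plastid ribosomal protein genes, 2 rose, 1 fell and 3 did not pass, and adjusted over the list alone 3 passed. AT4G01310 (protein L5) rose by 0.89 ± 0.13 (SE, adjusted p = 0.000220, and 0.0206 with averaging), and was at 0.44 on the values as deposited. AT3G13120 (S10) rose by 0.77 ± 0.19, not called with averaging (adjusted p = 0.119) or on the values as deposited (0.0659), and called in 27 of 32 alternatives. AT3G54210 (L17) fell by 0.35 ± 0.07, not called with averaging (0.0647), with equal medians (-0.01, adjusted p = 0.926) or after neighbour correction, where its fall was larger but no longer passed (-0.62, adjusted p = 0.204), and was also called in 27 of 32. AT1G64510 (S6) was at 0.68 ± 0.42 (adjusted p = 0.222, 0.0209 with the replicate block, 0.0213 without numbers 1 and 2, and 0.0556 with averaging and the block together) and AT1G29070 (L34) at -0.26 ± 0.49, a sign that turned without pam46 sample 4 (0.07). AT5G65220 (L29) was listed at 0 in all 12 samples. The list did not pass camera (adjusted p = 0.554, and 0.592 with an estimated correlation), while fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0409. Unlike camera, fry does not compare the members with other genes, and 1413 of all 3438 genes or features changed. Its result is for the 12 samples without averaging.

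Of the genes of photosynthesis in lists with fewer members, PSAN went from a deposited intensity of 6.21 ± 1.25 to 3.67 ± 0.612 (SD, n = 6, adjusted p = 0.000363, and 0.0403 with averaging). Its call ended with equal medians (-0.19, adjusted p = 0.317) and after neighbour correction (-0.36, 0.427). LHB1B2, a light-harvesting chlorophyll protein gene with near-identical copies and so uncertain, fell by 0.71 ± 0.15 (SE), was not called with averaging (adjusted p = 0.0702) and turned sign with equal medians (0.08). Its feature and that of PRK lie 1, 6 or 12 feature numbers from very bright features (mean intensity 27.1 and 19.3, against their own 25.1 and 2.84). LHB1B2 is about as bright itself. The array's layout is not given, so such features need not be adjacent, and spill was not excluded for single genes. PRK (1.29 with equal medians) kept its call with averaging (0.0256) and lost it with the replicate block added (0.0556). SBPASE, the sedoheptulose bisphosphatase of the same cycle, rose by 0.48 ± 0.17 (adjusted p = 0.0405), was not called with averaging (0.226) and was at -0.00093 on the values as deposited but at 1.57 after neighbour correction (adjusted p = 8.88e-05). It was called in 17 of 32 alternatives. Its call also ended when any of WT samples 1, 2, 5 and 6 or pam46 samples 1, 2, 4 and 5 was left out, with adjusted p from 0.0532 to 0.0791.

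In other plastid pathways, CHLM went from 0.588 ± 0.0772 to 0.169 ± 0.0374 (deposited intensity, SD, n = 6, adjusted p = 8.16e-05, and 0.0139 with averaging). AT1G74470, the geranylgeranyl reductase that makes the phytyl chain of chlorophyll, rose by 0.57 ± 0.12 (SE), was not called with averaging (adjusted p = 0.0663) and stood at 0.11 after neighbour correction (0.681). AT3G23940, the dihydroxyacid dehydratase of branched-chain amino acid synthesis, rose by 1.73 ± 0.21 (adjusted p = 8.52e-05, 0.0216 with averaging and 0.0563 with the replicate block added). AT3G58610, the ketol-acid reductoisomerase of that pathway, was at -0.23 ± 0.21 (adjusted p = 0.417), and passed on the values as deposited (-0.76, 0.0154). FATB, an acyl-carrier-protein thioesterase gene, rose by 0.47 ± 0.14 (adjusted p = 0.0207), was not called with averaging (0.175) or on the values as deposited (0.663), and turned to -0.12 after neighbour correction, with a call in 24 of 32 alternatives.

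**Figure D3:**
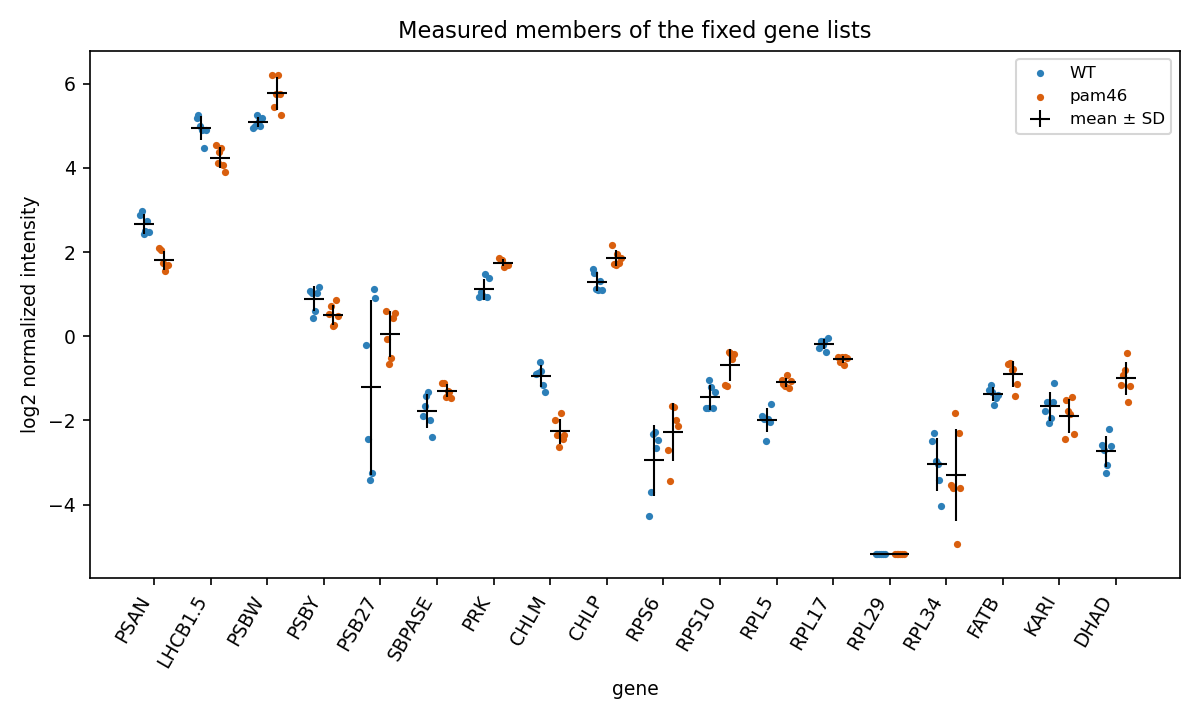
Log2 normalized intensity of the 18 measured members of the fixed gene lists in 6 WT and 6 pam46 samples, with mean ± SD. The pam46 values of CHLM lie below, and those of the dihydroxyacid dehydratase (DHAD) above, all WT values, while directions of PSBY and LHCB1.5 (LHB1B2) turned with equal medians, SBPASE on the values as deposited, and PSBY, RPL34, FATB and KARI after neighbour correction.

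**Figure D4:**
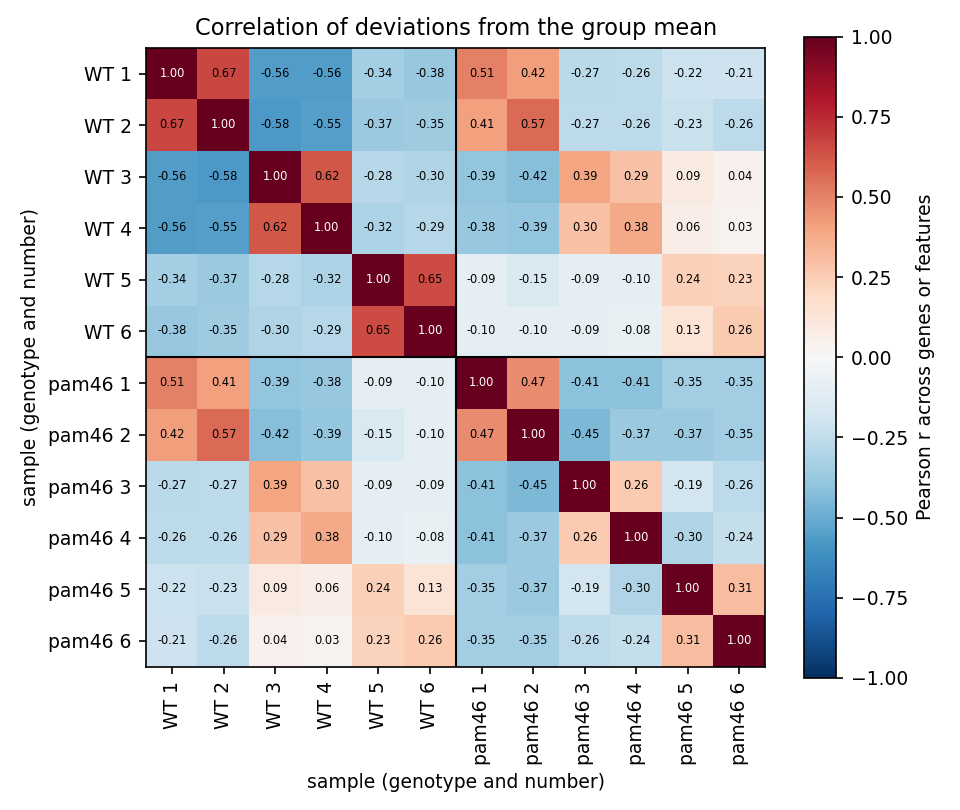
Pearson correlation across genes or features of each sample's deviation from its group mean, for all pairs of the 12 samples. Within a group, consecutive numbers (1 and 2, 3 and 4, 5 and 6) lie at 0.26 to 0.67 and other pairs at -0.58 to -0.19. Deviations from a mean of the same samples lower r within a group by construction.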

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

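In each group of 6, a sample was marked where its gap to the nearest other sample divided by the group's range exceeded Dixon's 95% critical value. This happened in 4 of 90 groups tested, and chance alone marks about 1 in 20. For AT3G06870, pam46 sample 2 was at -0.24 (log2 normalized intensity) and the other pam46 samples at 1.09 to 1.72. For AT2G31800, WT sample 5 was at -4.87 and the others at the floor of -5.17. For AT4G14330, WT sample 6 was at -3.94 and the others at -5.17 to -4.79. For AT1G11820, pam46 sample 6 was at -3.92 and the others at the floor. Where all other samples stand at the floor, as for AT2G31800 and AT1G11820, any sample above it is marked. The marks of these genes can therefore not be set against a rate of 1 in 20. All 4 genes stayed called with any 1 sample left out.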

How the results depend on the processing

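The random block, the pairs of numbers left out, the bright features' neighbours and the neighbour correction were chosen after seeing the data. Of 33 alternatives, 3 moved the count of 1413 changed genes by over 1.5 times: consecutive numbers averaged (587), these averages with the replicate block (693) and a random block for consecutive numbers (922). The first pair have fewer samples. Averaging numbers 1 and 4, 2 and 5, and 3 and 6, also 3 against 3, gave 1433 (688 higher, 745 lower). Each of these averages mixes 2 pairs of consecutive numbers and shares them with the other averages, which can narrow their spread. The count of 1433 therefore cannot tell whether fewer samples alone lowered the other counts, and the cause was not otherwise tested. A count that did not move could hold other calls. Neighbour correction called 1444, of which 925 were among the 1413 and 900 of these kept their direction. This correction also subtracts differences between WT and pam46 of the neighbours' own genes, which can itself end calls or turn signs. Of the 1413, 1095 were called on the values as deposited, 1098 with equal sums and 1197 with equal medians. The replicate block on all 12 samples gave 1658, 1355 of them shared with the 1413. Among 42 named and list genes it changed no call other than PSBY and AT1G64510, which passed with it but not with averaging added (adjusted p = 0.0984 and 0.0556), and no list. With 1 sample left out the count was 1315 to 1390, and with a pair of numbers left out of both groups 1164 to 1222. No list passed camera under any alternative run, and 1 of the 2 fixed lists passed fry, which asks another question. List tests were not run with the other prior, array weights or the random block, and the dim filter took 8 of the 42 genes out. Of the 42, 20 were called in every alternative that kept them, among them all 12 named rises, 6 named falls, CHLM and AT4G01310. Signs turned in these cases, and the cause was not tested. With equal medians PSBY was at 0.22 and LHB1B2 at 0.084, and on the values as deposited SBPASE at -0.00093. After neighbour correction PSBY was at 0.55 (passing as higher, adjusted p = 0.0473), AT1G29070 at 0.53, FATB at -0.12 and AT3G58610 at 0.28. AT1G29070, never called, was also at 0.020 with the floor at the 20th percentile, 0.19 without numbers 1 and 2, and -0.55 to 0.066 with 1 sample left out, turning only without pam46 sample 4. Fold changes of genes with a group near the floor depend on the floor: over all alternatives AT5G48130 ranged from -5.24 to -0.25, AT1G11820 from -5.30 to -1.23, AT2G31800 from 0.66 to 4.59 and AT1G22700 from 1.81 to 3.89.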

Other observations

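The lists in this part were written after the array's gene annotation was seen, and the tests of a scale factor, of a background and of consecutive numbers were chosen after the results they bear on. For comparison, 303 of the 691 features of 1 gene changed, 154 higher and 149 lower. Of 5 genes of the plastid NDH complex and its factors, 2 rose and 1 fell: CRR41 by 1.23 ± 0.16 (log2, SE, and 0.67 on the values as deposited) and CRR21, an RNA editing factor, by 0.80 ± 0.23, while the subunit gene NdhN fell by 0.31 ± 0.10 (-0.85 on the values as deposited). Of 11 thylakoid lumen and assembly genes, 2 rose and 3 fell. Among those not called, AT5G13410, AT5G52970 and CCB3 had all 6 WT samples at the floor and could not show a fall. AT4G24930, a lumen protein gene, rose by 1.99 ± 0.18 and AT1G74070 by 0.93 ± 0.20. SECE1, of the thylakoid Sec translocase, fell by 1.29 ± 0.11, AT1G76450 fell by 1.15 ± 0.31, and the photosystem II assembly factor gene LPA19 fell by 0.45 ± 0.16. With averaging CRR41, AT4G24930, AT1G74070 and SECE1 were called (adjusted p = 0.0161, 0.00308, 0.0418 and 0.00752) and CRR21, NdhN, AT1G76450 and LPA19 were not (0.168, 0.140, 0.0736 and 0.260). AT1G74070 was not called with the random block (adjusted p = 0.0559) or with averaging and the replicate block together (0.05003), where CRR41, AT4G24930 and SECE1 kept their calls. None of these genes turned sign with the scaling, but LPA19 was not called with equal medians (-0.07, adjusted p = 0.790), nor CRR21 and AT1G74070 on the values as deposited (0.105 each), where values lay lower in general and AT1G76450 was at -1.89.

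Of 18 pentatricopeptide repeat genes, whose proteins process organelle RNA, 6 rose and 3 fell, a balance that followed the scaling, with 2 rises and 4 falls on the values as deposited and 7 and 1 with equal medians. On the values as deposited CRR21 (adjusted p = 0.105), AT4G21170 (0.0771), OTP85 (0.287) and AT1G31790 (0.405) were not called as higher, and AT3G49740 passed as lower (-0.18, 0.0347). AT5G39980 rose by 1.37 ± 0.30 (not called with averaging, adjusted p = 0.0768) and AT3G22150 by 1.27 ± 0.22 (0.60 on the values as deposited), while AT4G14050 fell by 1.07 ± 0.17 (not called with equal medians, adjusted p = 0.0611) and OTP70 fell by 1.04 ± 0.13. AT3G26630 also fell, by 0.55 ± 0.12, and turned to 0.03 with equal medians. With averaging 1 of the rises and 2 of the falls were called. With the replicate block added, the rise of AT3G22150 kept its call (adjusted p = 0.0443). The falls of AT4G14050 (0.0512) and OTP70 (0.0503) lost theirs. Of 7 mTERF genes, of organelle gene expression, 2 rose, with mTERF9 (AT5G55580) at 1.46 ± 0.16, and 2 fell, with AT1G61990 at -1.02 ± 0.28 (adjusted p = 0.126 with averaging). With averaging 1 of these rises, mTERF9, and 0 of the falls were called. All 4 measured genes of glycosyl hydrolase family 9B had values below 0 under each scaling, and 2 of them fell: GH9B16 by 1.48 ± 0.22 and GH9B8 fell by 0.90 ± 0.23, the latter not called with averaging (adjusted p = 0.0519). The features of GH9B11 and GH9B12 (numbers 1490 and 1502) lie 12 apart, as do those of the mTERF falls AT1G61990 and AT1G62010 (1526 and 1538). At that distance features shared fold changes, as given below, so these genes may not count separately. Of 5 kinesin genes 2 rose and 1 fell, but on the values as deposited 1 rose and 2 fell, since AT3G20150 lost its call (adjusted p = 0.0693) and AT2G37420 passed as lower (-1.12, 0.00209), beside AT1G21730 (-0.57, and -1.13 as deposited). Of 4 tetrapyrrole genes 1 rose and 2 fell, with SIRB at -0.72 ± 0.18 (adjusted p = 0.118 with averaging), and of 7 photosynthesis genes pooled from the fixed lists 3 rose and 2 fell (3 and 0 with equal medians). On the values as deposited all 4 genes of family 9B and 3 mTERF genes passed as lower. None of 3 histone H3 genes and 1 of 4 calmodulin-like and IQ-domain genes (IQD22, -0.95 ± 0.31, adjusted p = 0.114 with averaging) passed, and the median and mean of each of these lists differ in sign. The histone gene AT5G65360 had all 6 WT samples at the floor and could not show a fall. The histone gene AT1G13370 passed as lower on the values as deposited (-0.44, adjusted p = 0.0230). None of the 10 lists passed camera, and 1 had an unadjusted p under 0.05 (family 9B, p = 0.0339, adjusted p = 0.339, and adjusted p = 0.979 with an estimated correlation). In fry, run for these lists on the quantile-normalized scale alone, 4 passed: family 9B and the pentatricopeptide repeat genes (adjusted p = 0.00733 each), the tetrapyrrole genes (0.0116) and the kinesins (0.0212). These fry results too are not a comparison with other genes.

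For 12 separate samples chance could be excluded for the count of 1413. Among 100 of the 462 splits of the 12 samples, 1, the real one, gave as many, and the highest other gave 12. Among the 32 splits that part every pair of equal numbers, again 1 gave as many, and the highest other gave 2. These splits take the 12 samples as exchangeable, which samples with consecutive numbers, deviating together, are not. With consecutive numbers averaged, 1 of 10 splits, the real one, gave as many as 587 and the highest other gave 0, but 10 splits are too few for a share under 0.05.

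Samples with consecutive numbers deviated together in both groups. The lowest correlation within such pairs lay 0.445 above the highest between them in the group where this gap was smaller, which describes the pattern and does not tell its source. Repeat readings of 1 array or hybridisation and another source of shared deviation, such as shared plants, cannot be told apart, since the labels do not say and nothing else was tested. Whatever the source, the 6 samples of a group are not independent, while the errors and adjusted p-values of 6 against 6 treat them so. The random block for consecutive numbers estimated a correlation of 0.614 within them and called 922. With repeat readings, 3 and not 6 samples per group carry the comparison, and the counts with averaging apply, 587 without and 693 with the replicate block.

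Deposited values in pam46 were lower at low and middle brightness, with a median log2 fold change of -0.80 in the second of 6 groups of features from dim to bright and -0.03 in the brightest. A single scale factor per sample is argued against by the gap of 0.769 between these groups. An additive background that differed between WT and pam46 may contribute: from the second to the fifth group the difference of WT minus pam46 grew 1.60 times (95% bootstrap interval 1.25 to 2.04) while the level grew 4.24 times. In the dimmest group the difference was 0.0127 against 0.0741 in the second, with a median log2 fold change of -0.20, less than a constant offset gives, though values bounded by 0 leave little room there. The interval reaches past the bound of 2 set for this explanation, so background and a change in many transcripts of middle abundance, which pam46 itself could bring, cannot be told apart.

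Features whose numbers lie 6 or 12 apart shared fold changes, with r of 0.187 and 0.175 across features (permutation p = 0.001 each, the smallest that 1000 shuffles can give), and features are not independent replicates. Lower correlations above the shuffled range occurred at other distances, among them 1 (0.128), 7 (0.104), 18 (0.108) and 24 (0.112), but not at 3, 9 or 10. Neighbouring genes on a chromosome are argued against, since features 6 or 12 apart with genes on different chromosomes correlated at 0.268 (144 pairs, 95% interval 0.110 to 0.414). Those with genes on the same chromosome were at -0.016 (92 pairs, -0.220 to 0.189). An uneven signal over the arrays, named below, would be expected in both kinds of pair, but the intervals overlap. Spill from very bright features as the whole cause is argued against, since r was 0.192 without them and their neighbours. Neighbours of bright features here are those 1, 6 or 12 numbers away, since the array's layout is not given. They were 1.71 times as bright as other features (permutation p = 0.001), so spill stays open for single genes. Among these are mTERF9 and OTP70 (mean intensity 0.458 and 0.693, with such bright features of 73.5 and 85.4). An uneven signal over the arrays is a candidate explanation, because deviations from the group mean also correlated at a distance of 6 within each of the 6 averages of consecutive numbers, whether or not each stands for 1 array, with a median r of 0.279 (0.177 to 0.443). After correction by features 6 and 12 numbers away, PSBW (0.43, adjusted p = 0.115), PSAN (-0.36, 0.427) and AT1G74470 (0.11, 0.681) lost their calls with smaller changes. AT3G54210 lost its call with a larger fall (-0.62, 0.204). The correction also subtracts differences between WT and pam46 of those features' own genes. It therefore cannot tell whether a gene owes part of its change to an uneven signal.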
